A study of Oryzias latipes with 8 samples.

How the data were processed

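Gene expression was measured by RNA sequencing in 8 libraries of sorted cells from the optic tectum of 1-month-old medaka: wdr12 GFP-positive cells (n = 3), wdr12 GFP-negative cells (n = 2) and ebf3 GFP-positive cells (n = 3). Per the protocol notes, tecta were pooled and dissociated, the cells sorted on a cytometer, and libraries made from a small RNA input and read from a single end. Per the submitters' processing notes, base calling used CASAVA 1.8.2, quality control FastQC 0.10.1, alignment TopHat2 and the differential test DESeq. The program that counted the reads, the genome build and the gene annotation are not given in the sources used here.

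The deposited count tables hold, per the file headers, a whole read count per gene and library, made by the authors without normalisation that the values show. The deposited tables of each comparison add a log2 fold change and a p-value with its adjusted form, computed by the authors with DESeq per the processing notes. The authors' sheets of changed genes give symbols for 4662 of 5043 listed medaka genes, and 229 genes carry more than 1 symbol over the sheets. Symbols were therefore at hand only for genes the authors listed, and 4658 tested genes carried one. The 3 count tables hold 17142 genes, of which 16957 had counts for all 8 libraries and 185 were in only 1 table and were not tested. The 131234 count cells present in more than 1 table were equal and 0 differed. The lowest total of a gene in a count table was 11, so genes with fewer counts had been removed. A complete table of the ebf3 line lists 20459 genes, 3127 of them at 0. One deposited list named for genes higher in wdr12 GFP-negative than in ebf3 GFP-positive cells holds the same 1500 genes as that for genes lower in wdr12 GFP-positive than in ebf3 GFP-positive cells, and the sheets of the ebf3 comparisons carry the opposite sign to the full tables; directions were taken from the full tables.

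Counts of the 3 groups were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the default filterByExpr filter, which left 15640 genes. Each of 3 comparisons was tested with the quasi-likelihood F test, two-sided, and adjusted by the Benjamini-Hochberg method over all genes tested, with calls at an adjusted p under 0.05. The common biological coefficient of variation was 0.514. The SE of a log2 fold change is its size over the square root of F. Levels are TMM-normalised CPM. The spread of replicates was taken as Pearson r of log2 CPM with a pseudocount of 1, and as the coefficient of variation of CPM. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

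Gene lists, 20 with 1146 symbols in all, were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and most of the other settings tried. The lists are ribosome biogenesis, ribosomal proteins, DNA replication, mitosis, DNA repair, neural progenitor and patterning factors, Notch pathway, Wnt pathway, Hedgehog and Fgf pathways, radial glia and astroglia, proneural and early neuronal factors, mature neuron and synapse, oligodendrocyte lineage, microglia and leukocytes, endothelium and mural cells, erythrocytes, meninges and fibroblasts, dissociation stress and immediate early genes, cilia and centrosome, and mRNA splicing. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 20 lists. The test ran over the 4658 genes with a symbol and not over all genes, because list members could be matched only among these; those genes were listed by the authors as changed in these libraries, so a list is compared with other changed genes. No list passed with a correlation estimated from the data.

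The naming rule took the genes behind the transgenes, the 10 largest called changes in each direction among genes with a symbol and a mean normalised count of at least 100, and up to 3 called members per list with the smallest adjusted p. A normalised count is CPM times the mean library size of 7.36 M counts. Not all of these are named in the text. Members named because they moved against their list, such as CIT, RPS6KA2, TP53BP1, RPA1 (1 of 2), DLK1 and onecut1, and further genes named for levels of plasma proteins and transmitters, were chosen after their values were seen; the former were not refitted under the alternatives. The liver set of 14 genes was also written after levels of apoa2 and tfa were seen.

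The analysis was tested on simulated data with the library sizes and spread of these libraries. Of 100 genes changed 2-fold, 2% were called with the right sign between the sorts of the wdr12 line, 4% between wdr12 GFP-positive and ebf3 GFP-positive cells and 2% between the controls; of 100 changed 4-fold, 36%, 47% and 30%. Of the calls, 0%, 7.3% and 11.1% fell on unchanged genes. Genes in step numbered 15175, 15175 and 15118. A simulated list of 30 genes raised 1.5-fold had an adjusted p = 4.09e-07 with camera, and 0 of 50 unchanged lists were called. The simulated genes were drawn independently, whereas correlations estimated from the data ran from -0.011 (Wnt pathway) to 0.818 (ribosomal proteins). The check therefore cannot show how often unchanged lists pass when their members move together. Only 200 genes were changed in each simulated set, fewer than were called in the real comparisons. The adjustment was therefore stricter, and these shares are not the power of the real fits. Against ebf3 GFP-positive cells, 27 of 42 ribosome biogenesis genes were called at a median log2 fold change of 1.01.

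Other settings chosen beforehand were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, other thresholds, only the 2 groups compared in the fit, a replicate block, other pseudocounts and filters for the spread, exact symbols, a filter of 10 on mean normalised counts for the lists, an estimated correlation and, for genes, leaving out each library. Added after the data were seen were list tests without each library, and fits without the 10 most abundant genes of each library, with the share of secreted liver proteins as a covariate, and without wdr12 GFP-positive replicate 1 and ebf3 GFP-positive replicate 3 together. DESeq2 size factors moved the groups by a log2 value of 0.002, -0.02 and 0.011 against TMM. Genes against both controls were those called in the same direction in both comparisons, set beside the number that independent lists would share and beside 20 simulated data sets without effects. The authors' sheets that set these genes beside other cell types were used only for counts of shared genes.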

Results

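RNA was sequenced from cells of the optic tectum, the visual centre of the midbrain, of 1-month-old medaka (Oryzias latipes). The cells were separated by fluorescence-activated sorting from fish of a pair of transgenic lines. In the first line the promoter of wdr12, a gene needed for ribosome biogenesis, drives green fluorescent protein (GFP) in the neuroepithelial cells. In the second line, named for ebf3, a transcription factor of neuronal differentiation, GFP marks progenitors that have left the cell cycle and neurons. The 8 libraries form 3 groups: wdr12 GFP-positive cells (n = 3), wdr12 GFP-negative cells (n = 2), which are described as holding cycling progenitors, neurons and glia, and ebf3 GFP-positive cells (n = 3). The design asks which genes set the neuroepithelial cells apart from the rest of the tectum and from cells that have left the cell cycle. Levels below are means ± SD of normalised CPM (counts scaled to a common library size), and log2 fold changes are given ± SE.

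The total counts per library ran from 8511784 to 11580753 in wdr12 GFP-positive, from 3497590 to 5798755 in wdr12 GFP-negative and from 5248124 to 7708238 in ebf3 GFP-positive cells. Libraries of 1 group correlated across genes with a mean Pearson r of 0.938 in wdr12 GFP-positive, 0.953 in wdr12 GFP-negative and 0.938 in ebf3 GFP-positive cells, and libraries of different groups with r from 0.772 to 0.885. These correlations are across genes, which are not independent replicates. The median coefficient of variation of a gene between replicates was 40.9%, 26.0% and 38.0% in the same order. The counts of replicates differed by more than sampling noise, at a chi-square per degree of freedom from 16.1 to 120.4, so no library was a copy of another of its group. Separate preparations of 1 sample would exceed sampling noise too. The first principal component, with 40.9% of the variance, placed wdr12 GFP-positive libraries from -127 to -81 and all others from 44.2 to 81.2. On the second, with 22.1%, wdr12 GFP-positive replicate 1 stood at 79.9 and replicates 2 and 3 at -37.8 and -32.1, while ebf3 GFP-positive replicate 3 stood at -4.70 and the other two at 82.0 and 51.2. Nothing in the labels states whether the replicates came from separate pools of fish. The p-values therefore measure only the spread between these samples, which may be technical.

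The genes behind the transgenes were examined first. wdr12 (ENSORLG00000003110) stood at 70.1 ± 25.7 CPM in wdr12 GFP-positive cells, 23.6 ± 2.98 in wdr12 GFP-negative cells and 23.3 ± 4.27 in ebf3 GFP-positive cells. It was higher in the GFP-positive cells of its line than in the GFP-negative cells by a log2 fold change of 1.57 ± 0.38 (adjusted p = 0.00786), and higher than in ebf3 GFP-positive cells by 1.59 ± 0.33 (adjusted p = 0.002). The first of these calls was lost without wdr12 GFP-negative replicate 1 (adjusted p = 0.0626) and without replicate 2 (adjusted p = 0.109). ebf3 (ENSORLG00000005870) was most abundant in the cells of its own line, at 2524 ± 240.5 CPM against 406 ± 148 in wdr12 GFP-positive and 659 ± 3.84 in wdr12 GFP-negative cells. It was lower in wdr12 GFP-positive than in ebf3 GFP-positive cells (log2 fold change -2.64 ± 0.33, adjusted p = 4.66e-05) and did not pass the test between the sorts of the wdr12 line (-0.70 ± 0.34, adjusted p = 0.181). Between wdr12 GFP-negative and ebf3 GFP-positive cells its log2 fold change was -1.94 ± 0.37 (adjusted p = 0.0071), a call lost without wdr12 GFP-negative replicate 1 (adjusted p = 0.0988) or 2 (adjusted p = 0.0976).

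**Figure D1:**
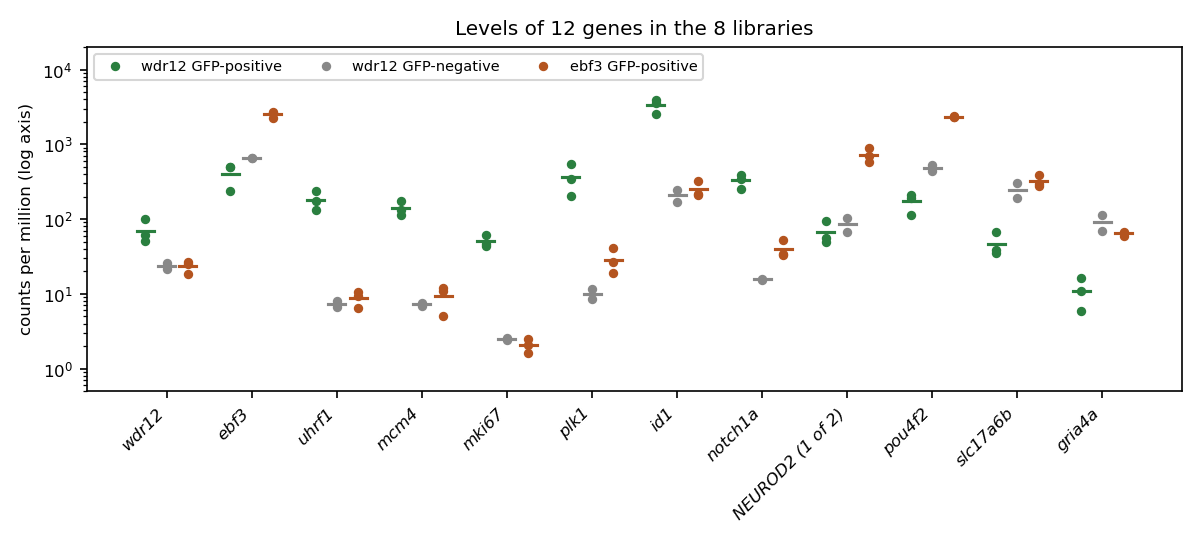
CPM (log axis) of 12 genes in the 8 libraries; each point is a library and each bar the mean of its group. The 3 wdr12 GFP-positive libraries lie above the other 5 for wdr12, uhrf1, mcm4, mki67, plk1, id1 and notch1a and below them for pou4f2, slc17a6b and gria4a.

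Against the GFP-negative cells of the same line, the wdr12 GFP-positive cells expressed the machinery of cell division at many times the level. plk1 (ENSORLG00000009603), a kinase of mitotic entry and spindle assembly, stood at 362 ± 171 CPM (SD, n = 3) against 9.996 ± 2.14 (n = 2), a log2 fold change of 5.17 ± 0.52 (adjusted p = 5.12e-05). mcm4 (ENSORLG00000017467), a subunit of the replicative helicase, stood at 139 ± 30.9 against 7.24 ± 0.527 CPM (4.27 ± 0.45, adjusted p = 5.75e-05), and uhrf1 (ENSORLG00000006710), which maintains DNA methylation at replication, at 182 ± 53.2 against 7.32 ± 0.817 CPM (4.63 ± 0.42, adjusted p = 3.8e-05). Of 50 mitosis genes with a symbol, and so listed by the authors as changed, 48 were higher, 1 was lower and 1 did not pass. Adjusted over the list alone, 48 were higher and 1 lower, and the median log2 fold change was 3.90. Their leading members were nuf2 of the kinetochore (4.54 ± 0.43), the mitotic kinesin KIF23 (1 of 2) (4.86 ± 0.45) and plk1. The 1 lower member was CIT, a kinase of late cell division (-2.33, adjusted p = 0.000943). Of 50 DNA replication genes, 48 were higher and 2 did not pass, with 49 higher adjusted over the list alone and a median of 2.97. The list test gave adjusted p = 1.46e-15 for mitosis and 4.47e-14 for DNA replication, and adjusted p = 0.382 with an estimated correlation for both. Of 47 DNA repair genes, 40 were higher and 1 was lower (44 and 1 adjusted over the list alone), with a median of 1.97 (adjusted p = 4.75e-09, and adjusted p = 0.382 with an estimated correlation). h2afx, the histone variant phosphorylated at DNA breaks, and fanci, of the Fanconi pathway of crosslink repair, had log2 fold changes of 2.88 ± 0.35 and 2.84 ± 0.40. Of 28 cilia and centrosome genes, 19 were higher and 1 was lower (23 and 1 adjusted over the list alone), with a median of 1.66 (adjusted p = 1.14e-05, and adjusted p = 0.382 with an estimated correlation). Among these were plk4, the kinase of centriole duplication (3.59 ± 0.54), and haus1 of the spindle augmin complex (3.02 ± 0.44).

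Genes of ribosome production were higher in the wdr12 GFP-positive than in the GFP-negative cells as well. All but 2 of 42 ribosome biogenesis genes passed, with 40 higher, none lower and a median log2 fold change of 1.41 (42 higher adjusted over the list alone). fbl and nop58, components of the box C/D particles that methylate ribosomal RNA, were higher by 2.33 ± 0.36 and 2.32 ± 0.38, and utp15 of the small-subunit processome by 2.33 ± 0.37. The 52 genes of the ribosomal protein list took 17.2 ± 0.956% of the counts in wdr12 GFP-positive, 8.03 ± 0.862% in wdr12 GFP-negative and 13.98 ± 1.83% in ebf3 GFP-positive cells. Of these, 51 were higher in wdr12 GFP-positive than in GFP-negative cells, both over all genes and adjusted over the list alone, with a median of 1.42. The 1 lower member, RPS6KA2 (-2.13, adjusted p = 0.0346), is a kinase named for its ribosomal substrate and not part of the ribosome. The list test gave adjusted p = 1.68e-08 for both lists, and adjusted p = 0.389 with an estimated correlation for ribosome biogenesis and 0.492 for ribosomal proteins. Of 31 mRNA splicing genes, 26 were higher and none lower (30 adjusted over the list alone), with a median of 1.46 (adjusted p = 5.87e-06, and adjusted p = 0.464 with an estimated correlation). Examples were sf3b3 of the U2 particle (1.83 ± 0.32) and snrpf of the Sm ring (1.94 ± 0.39).

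Regulators of neural progenitors and the Notch pathway were higher in the same cells. id1 (ENSORLG00000013719), an inhibitor of proneural factors, stood at 3337 ± 717 CPM against 206 ± 54.8 (4.02 ± 0.41, adjusted p = 5.12e-05), and SOX2 (ENSORLG00000001780), a stem cell transcription factor, at 401 ± 97.3 against 25.8 ± 6.57 (3.96 ± 0.40, adjusted p = 5.31e-05). Of 27 progenitor and patterning factors, 18 were higher and 1, id2a, was lower (20 and 1 adjusted over the list alone), with a median of 2.15 (adjusted p = 6.31e-05, and adjusted p = 0.382 with an estimated correlation). The receptor notch1a was higher by 4.39 ± 0.40 (adjusted p = 3.8e-05) and its ligand dlb by 3.99 ± 0.44. Of 11 Notch genes, 10 were higher and 1, DLK1, was lower, in both adjustments, with a median of 2.46 (adjusted p = 0.000645, and adjusted p = 0.382 with an estimated correlation). In the Wnt list 5 of 13 were higher and 1 lower, and in the Hedgehog and Fgf list 5 of 9 were higher and 1 lower, the same counts as when adjusted over the list alone, and neither list passed (adjusted p = 0.22 and 0.0593). Higher members included the ligand WNT7A (3.18 ± 0.43), the receptor fzd10 (2.61 ± 0.34), the secreted Wnt inhibitor sfrp5 (3.70 ± 0.60) and the Hedgehog co-receptor boc (3.40 ± 0.39). Among proneural and early neuronal factors, 2 of 16 were higher and 4 lower in both adjustments, and the list did not pass (adjusted p = 0.646). Its members neurod4, a proneural factor of committed progenitors (3.65 ± 0.42), and elavl2, an RNA-binding protein of neurons (-2.83 ± 0.34), lay in opposite directions.

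Genes of mature neurons were lower in the wdr12 GFP-positive than in the GFP-negative cells. Of 65 neuron and synapse genes, 62 were lower, none was higher and 3 did not pass (63 lower adjusted over the list alone), with a median log2 fold change of -2.55 (adjusted p = 9.5e-14, and adjusted p = 0.389 with an estimated correlation). gria4a, a glutamate receptor subunit, stood at 11.1 ± 5.26 against 91.6 ± 32.0 CPM (-3.05 ± 0.39, adjusted p = 0.000141), and ENO2 (2 of 2), the neuronal enolase, at 27.7 ± 17.4 against 272 ± 96.8 CPM (-3.30 ± 0.43, adjusted p = 0.000146). slc32a1, the vesicular transporter of GABA and glycine, was lower by -2.23 ± 0.30.

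Most of the 10 largest decreases among named genes belonged to red blood cell genes. The gene chp2 (-7.14 ± 0.925), GATA-1 and the globin genes named GB were among the 10 but not in the fixed erythrocyte list. A globin named GB (ENSORLG00000003046) stood at 179 ± 150 CPM in wdr12 GFP-positive and 34610 ± 32000 CPM in wdr12 GFP-negative cells (-7.59 ± 0.81, adjusted p = 6.17e-05). ALAS2, the first enzyme of erythroid haem synthesis (-7.09 ± 0.69), cahz, an erythroid carbonic anhydrase (-7.43 ± 0.72), and GATA-1, the erythroid transcription factor (-6.20 ± 0.67), went with it. Of 10 erythrocyte genes, 8 were lower in both adjustments and none higher, with a median of -4.53 (adjusted p = 0.000645, and adjusted p = 0.382 with an estimated correlation). The 5 globin genes named GB took 4.27% and 15.7% of the counts of the GFP-negative libraries, against at most 0.0842% in any wdr12 GFP-positive library. Globins form a gene family with near-identical copies among which reads could be split, so the value of any single globin is uncertain, and the same holds for genes named as 1 of several copies.

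Markers of other cell types did not pass as lists between the sorts of the wdr12 line. For radial glia and astroglia 0 of 13 genes were higher and 1, ndrg2, was lower (adjusted p = 0.845). For oligodendrocytes 2 of 13 were higher and 3 lower (adjusted p = 0.827), for endothelium and mural cells 2 of 10 were higher and 3 lower (adjusted p = 0.817), and for microglia and leukocytes 1 of 19 was higher and 1 lower (adjusted p = 0.817). Meninges and fibroblasts had 1 of 9 higher (adjusted p = 0.619), and stress and immediate early genes 6 of 22 higher and 4 lower (adjusted p = 0.646). Adjusted over the list alone, the counts were the same for glia, oligodendrocytes and meninges, 4 and 3 for endothelium, 0 and 0 for microglia, and 7 and 6 for stress genes. Within these lists cnp, a myelin-associated phosphodiesterase, was higher (3.01 ± 0.35), whereas the myelin proteolipid plp1b was lower (-2.81 ± 0.81, adjusted p = 0.0222), a call lost without GFP-negative replicate 1 (adjusted p = 0.168) and without GFP-positive replicate 1 (adjusted p = 0.0728) or 2 (adjusted p = 0.0656). The 2 higher members of the endothelium list were cldn5a, a tight junction gene (4.14 ± 0.51), and notch3 (2.94 ± 0.32), which is also in the Notch list. The endothelial cadherin cdh5 was lower (-2.60 ± 0.47). Secreted liver proteins, a set written after the levels of apoa2 and tfa were seen, took 7.004 ± 4.17% of the counts of wdr12 GFP-positive and 2.31 ± 0.584% of those of wdr12 GFP-negative cells.

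Over all genes tested between the sorts of the wdr12 line, edgeR's quasi-likelihood test called 1551 of 15640 higher and 1539 lower in the GFP-positive cells (adjusted p under 0.05, two-sided). The counts fell to 557 and 891 without GFP-negative replicate 1 and to 704 and 785 without GFP-negative replicate 2, where the remaining library is assumed to vary like the others. Gene symbols came from the authors' lists of changed genes, so list members were chosen on these libraries and their counts are not independent evidence of a direction. Of all 4658 tested genes with a symbol, 1394 were higher and 1429 lower in this comparison. The counts were 1766 and 1483 in wdr12 GFP-positive against ebf3 GFP-positive cells, and 432 and 288 in wdr12 GFP-negative against ebf3 GFP-positive cells. The median log2 fold changes of the genes with a symbol were 0.313, 0.279 and 0.19 in the same order of comparisons.

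**Figure D2:**
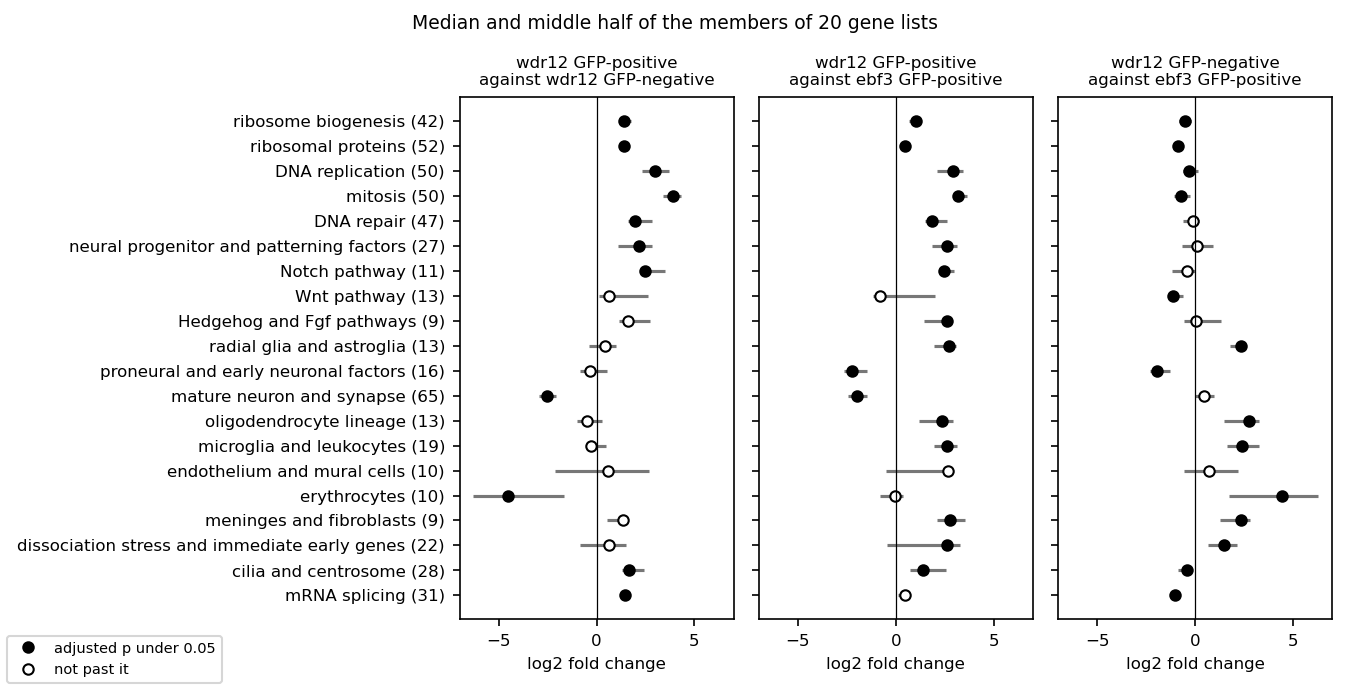
Median log2 fold change (points) and interquartile range (bars) of the members of 20 gene lists in each comparison, with the number of members in brackets; filled points are lists with an adjusted p under 0.05. Mitosis lies at 3.90 and 3.20 in the comparisons with wdr12 GFP-positive cells, and mature neuron and synapse genes at -2.55 and -1.99.

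**Figure D3:**
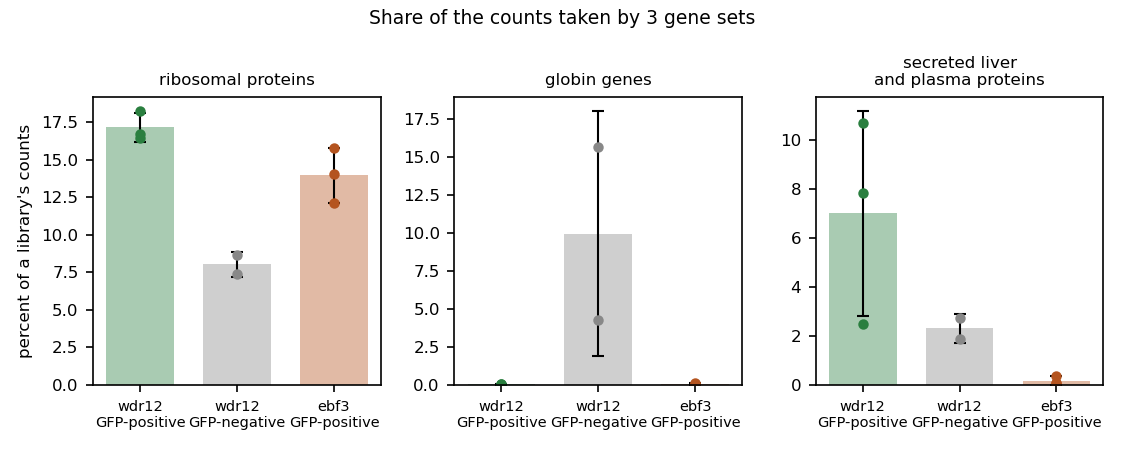
Percent of each library's counts (vertical axis) taken by ribosomal protein genes, by 5 globin genes and by 8 secreted liver and plasma protein genes; points are libraries, bars group means and lines ± SD. The globin share was 4.27% and 15.7% in the wdr12 GFP-negative libraries, and the liver share ran from 2.47% to 10.7% in the wdr12 GFP-positive libraries.

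Against the ebf3 GFP-positive cells, described as having left the cell cycle, the wdr12 GFP-positive cells again stood far higher in cell division genes. mki67 (ENSORLG00000004358), the Ki-67 proliferation marker, stood at 50.0 ± 9.31 CPM (SD, n = 3) against 2.06 ± 0.446 (n = 3), a log2 fold change of 4.601 ± 0.39 (adjusted p = 9.5e-06). uhrf1 was higher by 4.38 ± 0.34 (adjusted p = 4.08e-06), mcm4 by 3.91 ± 0.36 (adjusted p = 1.06e-05) and rrm1 (1 of 2), a subunit of the enzyme that makes deoxynucleotides, by 3.48 ± 0.34. Of the 50 mitosis genes 49 were higher and none lower in both adjustments, with a median of 3.20. Of the 50 DNA replication genes 48 were higher and 1, RPA1 (1 of 2), was lower (49 and 1 adjusted over the list alone), with a median of 2.93. The list test gave adjusted p = 1.34e-11 and 2.79e-11, and adjusted p = 0.375 with an estimated correlation for both. In the DNA repair list 41 of 47 were higher and 1, TP53BP1, was lower (42 and 1 adjusted over the list alone), with a median of 1.83 (adjusted p = 6.52e-07, and adjusted p = 0.375 with an estimated correlation). The crosslink repair gene fancd2 was higher by 4.16 ± 0.46. In the cilia and centrosome list 17 of 28 were higher and 2 lower (20 and 2 adjusted over the list alone), with a median of 1.36 (adjusted p = 0.00275, and adjusted p = 0.375 with an estimated correlation). The gene rfx4, a ciliary transcription factor, was higher by 4.31 ± 0.58.

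The ribosome lists differed less in this comparison. Of 42 ribosome biogenesis genes 27 were higher and none lower (33 adjusted over the list alone), with a median of 1.01 (adjusted p = 0.000389, and adjusted p = 0.461 with an estimated correlation). nop56, a partner of nop58 in the box C/D particle, was higher by 1.57 ± 0.29 and polr1a, the largest subunit of RNA polymerase I, by 1.59 ± 0.30. Only 4 of 52 ribosomal protein genes were higher over all genes and 3 adjusted over the list alone. Their median was 0.49, against 0.28 for all tested genes with a symbol. The ribosomal protein list passed at adjusted p = 0.0276, and had adjusted p = 0.76 with an estimated correlation. It was lost without wdr12 GFP-positive replicate 1 (0.0879), ebf3 GFP-positive replicate 1 (0.125) or ebf3 GFP-positive replicate 3 (0.148). The ribosomal stalk protein rplp0 was higher by 1.34 ± 0.29 (adjusted p = 0.00285). For mRNA splicing 2 of 31 genes were higher (1 adjusted over the list alone), and the list did not pass (adjusted p = 0.25).

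Progenitor regulators were higher than in the ebf3 GFP-positive cells, and neuronal fate factors lower. Of 27 progenitor and patterning factors 21 were higher and 3 lower (23 and 3 adjusted over the list alone), with a median of 2.60 (adjusted p = 0.000616, and adjusted p = 0.375 with an estimated correlation). id1 was higher by 3.73 ± 0.34 and SOX2 (ENSORLG00000001780) by 3.36 ± 0.33, while id2a, another inhibitor of proneural factors, was lower (-3.21 ± 0.35). Of 11 Notch genes 9 were higher and 1, DLK1, was lower in both adjustments, with a median of 2.47 (adjusted p = 0.0076, and adjusted p = 0.375 with an estimated correlation). The receptor notch1a was higher by 3.06 ± 0.31 and notch3 by 2.70 ± 0.27. The Hedgehog and Fgf list had 7 of 9 higher and 1, fgf13b, lower in both adjustments, with a median of 2.63 (adjusted p = 0.0239, and adjusted p = 0.375 with an estimated correlation), and included fgfr2, an Fgf receptor (2.92 ± 0.31), and smo, the Hedgehog signal transducer (3.10 ± 0.45). The Wnt list had 3 of 13 higher and 5 lower (4 and 7 adjusted over the list alone) and did not pass (adjusted p = 0.427). Its median was -0.81 and its mean 0.043. Of 16 proneural and early neuronal factors 12 were lower and 2, neurod4 and onecut1, were higher (13 and 2 adjusted over the list alone), with a median of -2.23 (adjusted p = 0.000236, and adjusted p = 0.375 with an estimated correlation). pou4f2 (ENSORLG00000007412), a factor of projection neurons, stood at 173 ± 51.6 against 2311 ± 45.5 CPM (-3.74 ± 0.32, adjusted p = 9.5e-06), and NEUROD2 (1 of 2), a factor of neuronal differentiation, at 66.2 ± 25.1 against 726 ± 163 CPM (-3.45 ± 0.35, adjusted p = 1.37e-05).

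Genes of acetylcholine and of neuropeptides were among the 10 largest decreases against the ebf3 GFP-positive cells, beside gfra1a, sp5l, MAF (1 of 2), MAF (2 of 2), NXPH3 and CPNE5 (1 of 2). SLC18A3 (ENSORLG00000009439), the vesicular acetylcholine transporter, stood at 1.34 ± 0.901 against 34.0 ± 5.68 CPM (-4.67 ± 0.50, adjusted p = 1.8e-05), and CHAT (2 of 2), the enzyme that makes acetylcholine, at 6.33 ± 3.77 against 103 ± 16.6 CPM (-4.03 ± 0.42, adjusted p = 1.8e-05). The neuropeptide genes UCN3 (-5.46 ± 0.95, adjusted p = 0.000602) and CCK (1 of 2) (-4.01 ± 0.45) and the receptor of glial-derived neurotrophic factor gfra1a (-4.58 ± 0.34, adjusted p = 4.08e-06) were also lower. In the neuron and synapse list 54 of 65 genes were lower and none higher (59 adjusted over the list alone), with a median of -1.99 (adjusted p = 1.79e-11, and adjusted p = 0.375 with an estimated correlation). slc17a6b, the vesicular glutamate transporter, was lower by -2.77 ± 0.33. The GABA genes slc32a1, gad1b and gad2 were not called, with log2 fold changes of -0.67, -0.67 and -0.43 (adjusted p = 0.0956, 0.302 and 0.503).

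The wdr12 GFP-positive cells also stood above the ebf3 GFP-positive cells in markers of several other cell types, as did the wdr12 GFP-negative cells. For the latter the medians were 2.34 (radial glia), 2.76 (oligodendrocytes), 2.39 (microglia) and 2.35 (meninges). Higher levels than in ebf3 GFP-positive cells were therefore seen in both sorts of the wdr12 line. None of these lists passed between those sorts, which does not show equal levels. The medians of GFP-positive against GFP-negative cells were 0.426, -0.483, -0.265 and 1.33 in the same order. Radial glia and astroglia genes were higher for 11 of 13 and lower for 1, ndrg2, in both adjustments, with a median of 2.70 (adjusted p = 0.00641, and adjusted p = 0.386 with an estimated correlation). The gene cx43, the astroglial connexin, was higher by 3.45 ± 0.46. For oligodendrocytes 10 of 13 were higher in both adjustments (median 2.38, adjusted p = 0.00641), and for microglia and leukocytes 15 of 19 were higher and 2 lower (16 and 3 adjusted over the list alone; median 2.62, adjusted p = 0.00295). For meninges and fibroblasts 7 of 9 were higher in both adjustments (median 2.74, adjusted p = 0.00641). These 3 lists each had adjusted p = 0.375 with an estimated correlation. Examples were mag, a myelin glycoprotein (2.90 ± 0.50), cd74b, a chaperone of antigen presentation (2.72 ± 0.33), and dcn, a proteoglycan of connective tissue (5.70 ± 0.55, adjusted p = 1.2e-05). Endothelium had 7 of 10 higher and 2 lower in both adjustments and did not pass (adjusted p = 0.216), and 0 of 10 erythrocyte genes were called by edgeR (adjusted p = 0.568). Stress and immediate early genes had 15 of 22 higher and 3 lower in both adjustments, with a median of 2.61 (adjusted p = 0.0239, and adjusted p = 0.413 with an estimated correlation). JUN (2 of 2) was higher by 3.64 ± 0.43.

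The 10 largest increases were those of vsg1, si:dkey-4e7.3 (1 of 2), hpdb, c7a, slc5a5, osr1, tat, si:dkey-103i16.2, ces2 and krt15. hpdb and tat, enzymes of tyrosine breakdown, were higher by 6.58 ± 0.57 (adjusted p = 9.5e-06) and 6.20 ± 0.70 (adjusted p = 2.34e-05), and c7a, a complement component, by 6.46 ± 0.66. Of 14 liver genes, a set written after the levels of apoa2 and tfa were seen, 13 were higher than in ebf3 GFP-positive cells with a median of 5.28. apoa2, an apolipoprotein of plasma lipid particles, stood at 35479 ± 20716 CPM in wdr12 GFP-positive, 8587 ± 352 in wdr12 GFP-negative and 676 ± 583 in ebf3 GFP-positive cells. The secreted liver proteins took 2.47%, 7.85% and 10.7% of the counts of the 3 wdr12 GFP-positive libraries, against 0.175 ± 0.177% in ebf3 GFP-positive cells. The keratin krt15 was higher by 5.97 ± 1.63 (adjusted p = 0.0139), a call lost without ebf3 GFP-positive replicate 1 (0.0585) or 2 (0.0536).

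edgeR called 1983 of 15640 genes higher and 1688 lower in wdr12 GFP-positive than in ebf3 GFP-positive cells (adjusted p under 0.05, two-sided). The line and the sort change together in this comparison, so their effects cannot be told apart. With the share of secreted liver proteins as a covariate, chosen after that share was seen, the counts were 271 and 124. The share is largely confounded with the line. Of 78 named results of this comparison 49 lost their call in that fit, 17 of them with a log2 fold change at least as large as before, such as celf4 at -2.62 against -2.45.

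Between the control populations, the wdr12 GFP-negative cells were higher in red blood cell, glial and immune genes and lower in neuronal fate factors. ALAS2 stood at 1131 ± 1078 CPM (SD, n = 2) against 6.71 ± 3.99 (n = 3), a log2 fold change of 7.41 ± 0.70 (adjusted p = 0.000148), and the globin GB (ENSORLG00000003046) was higher by 7.73 ± 0.81 (adjusted p = 0.000178). Of 10 erythrocyte genes 8 were higher and none lower in both adjustments, with a median of 4.43 (adjusted p = 8.18e-05, and adjusted p = 0.374 with an estimated correlation). For radial glia and astroglia 8 of 13 were higher and none lower (11 adjusted over the list alone; median 2.34, adjusted p = 8.18e-05, and adjusted p = 0.403 with an estimated correlation), with cx43 higher by 2.95 ± 0.48 and the growth factor ptn by 2.61 ± 0.47. For oligodendrocytes 9 of 13 were higher and 1, cnp, was lower (11 and 1 adjusted over the list alone; median 2.76, adjusted p = 0.000376, and adjusted p = 0.374 with an estimated correlation), with mag higher by 3.27 ± 0.53. For microglia and leukocytes 13 of 19 were higher and none lower (15 and 1 adjusted over the list alone; median 2.39, adjusted p = 9.14e-06, and adjusted p = 0.374 with an estimated correlation). The phosphatase ptpn6 of blood cells was higher by 4.12 ± 0.49 (adjusted p = 0.000495), cd74a by 3.27 ± 0.43 and cd74b by 3.12 ± 0.35. Meninges and fibroblasts had 2 of 9 higher (6 adjusted over the list alone; median 2.35, adjusted p = 0.00152, and adjusted p = 0.403 with an estimated correlation), with dcn higher by 3.91 ± 0.56, and stress genes 7 of 22 higher and 1 lower (13 and 2 adjusted over the list alone; median 1.48, adjusted p = 0.00105, and adjusted p = 0.403 with an estimated correlation). CNDP1, a dipeptidase, was higher by 6.29 ± 1.09.

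Factors of neuronal differentiation were lower in the wdr12 GFP-negative than in the ebf3 GFP-positive cells. NEUROD2 (1 of 2) stood at 85.1 ± 26.2 against 726 ± 163 CPM (-3.09 ± 0.41, adjusted p = 0.000852), and 12 of 16 proneural and early neuronal factors were lower and none higher (14 and 1 adjusted over the list alone), with a median of -1.96 (adjusted p = 4.07e-08, and adjusted p = 0.374 with an estimated correlation). coe2, a relative of ebf3, was lower by -2.56 ± 0.37, casz1 (1 of 2), a zinc finger factor, by -2.78 ± 0.34 and sp5l, a target of Wnt signals, by -2.92 ± 0.45. The Wnt list was lower for 4 of 13 genes and higher for none (7 and 0 adjusted over the list alone; median -1.15, adjusted p = 0.000684, and adjusted p = 0.255 with an estimated correlation), with the Wnt effector TCF7L1 at 36.2 ± 10.9 against 171 ± 23.3 CPM (-2.23 ± 0.33, adjusted p = 0.00192). The patterning factor lhx2b was lower by -2.52 ± 0.34, in a progenitor list that did not pass (2 of 27 higher and 5 lower, 4 and 5 adjusted over the list alone, adjusted p = 0.648, median 0.11 with the test directed down). The neuron and synapse list did not pass, with 4 of 65 genes higher in both adjustments (adjusted p = 0.149).

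Small shifts over many genes gave the remaining list results of this comparison. Ribosomal protein genes had a median of -0.89 with 1 of 52 lower over all genes and 40 adjusted over the list alone (adjusted p = 3.97e-10, and adjusted p = 0.474 with an estimated correlation). Splicing genes had a median of -1.02 with 5 of 31 lower (25 adjusted over the list alone; adjusted p = 2.98e-08, and adjusted p = 0.418 with an estimated correlation), and ribosome biogenesis genes a median of -0.53 with 3 of 42 lower (4 adjusted over the list alone; adjusted p = 8.18e-05, and adjusted p = 0.481 with an estimated correlation). Mitosis genes had a median of -0.72 with 2 of 50 higher and 1 lower (2 and 6 adjusted over the list alone, list test adjusted p = 0.000376, and adjusted p = 0.481 with an estimated correlation). They took 0.0806 ± 0.00955% of the counts in wdr12 GFP-negative and 0.115 ± 0.00277% in ebf3 GFP-positive cells. As a list, mitosis genes were therefore not higher in the group described as holding cycling progenitors. The DNA replication list passed with 0 of 50 members called by edgeR in both adjustments (median -0.33, adjusted p = 0.0387, and adjusted p = 0.745 with an estimated correlation), and was lost without wdr12 GFP-negative replicate 1 (0.0827), without ebf3 GFP-positive replicate 3 (0.117) and with exactly matching symbols (0.0746). The cilia list passed with 1 of 28 higher and 1 lower (1 and 5 adjusted over the list alone; median -0.41, adjusted p = 0.0387, and adjusted p = 0.533 with an estimated correlation), and was lost without wdr12 GFP-negative replicate 2 (0.145) or ebf3 GFP-positive replicate 3 (0.143). The lists that did not pass were DNA repair (0 of 47 higher and 1 lower in both adjustments, adjusted p = 0.127), Notch (0 of 11 higher and 3 lower in both adjustments, adjusted p = 0.0954), Hedgehog and Fgf (2 of 9 higher in both adjustments, adjusted p = 0.553) and endothelium (4 of 10 higher in both adjustments, adjusted p = 0.318).

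Between the control populations edgeR called 494 of 15640 genes higher and 307 lower in wdr12 GFP-negative cells (adjusted p under 0.05, two-sided). The counts were 184 and 25 without wdr12 GFP-negative replicate 1, 133 and 36 without replicate 2, 213 and 84 without ebf3 GFP-positive replicate 1, 274 and 140 without ebf3 GFP-positive replicate 2, and 753 and 576 without wdr12 GFP-positive replicate 1, which enters the estimate of the spread. Of 68 called genes that the naming rule took here, 46 were lost when some 1 library was left out; of the called genes named above for this comparison, ebf3 and cnp (adjusted p = 0.0662 without wdr12 GFP-negative replicate 1) were among these and the others were not. With the share of secreted liver proteins as a covariate, chosen after that share was seen, the counts were 2 and 2, and 63 of 70 named results lost their call, among them ALAS2 (log2 fold change 5.48, adjusted p = 0.23). The line and the GFP gate change together between the controls too, so their effects cannot be told apart.

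Genes that set the wdr12 GFP-positive cells apart from both controls were counted last. Against both controls 939 genes were higher and 1106 lower, among them plk1, mcm4, uhrf1, id1 and notch1a on the higher side and gria4a and slc17a6b on the lower. Independent lists of the same lengths would share 197 and 166 genes. The mean overlap in 20 simulated data sets without effects was 0 and 0.05 genes. Such sets give almost no calls, so an overlap near 0 was fixed beforehand. It is no reference for lists of this length that share libraries. Another 8 genes were higher than in wdr12 GFP-negative but lower than in ebf3 GFP-positive cells, and 5 the reverse. Both comparisons share the 3 wdr12 GFP-positive libraries, too few to split, so part of the excess over independent lists may come from the shared libraries. Without genes that differed between the controls, 850 higher and 1084 lower remained. With the share of secreted liver proteins as a covariate the counts were 254 and 113. The shared counts were 473 and 692 without wdr12 GFP-negative replicate 1 and 483 and 640 without replicate 2.

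The calls were set beside the authors' deposited lists of changed genes, which require an adjusted p under 0.05 and a 2-fold change. The authors' deposited table lists 1624 genes higher and 1712 lower in wdr12 GFP-positive than in GFP-negative cells, of which 1410 and 1508 were called here. Against ebf3 GFP-positive cells the authors' deposited table lists 1921 and 1500, of which 1862 and 1485 were called. Between the controls the authors' deposited table lists 895 higher and 711 lower in wdr12 GFP-negative cells, of which 484 and 306 were called. No listed gene was called here in the opposite direction.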

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

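The fits with the share of secreted liver proteins as a covariate, without the 10 most abundant genes of each library, and without wdr12 GFP-positive replicate 1 and ebf3 GFP-positive replicate 3 together, and the list tests without each library, were chosen after the results were seen. With the liver share as a covariate, which is largely confounded with the line and costs a coefficient, 271 genes were higher and 124 lower in wdr12 GFP-positive than in ebf3 GFP-positive cells, 2 and 2 between the controls, and 254 and 113 against both controls, while the counts between the sorts of the wdr12 line were 1867 and 1626 against 1551 and 1539. The same covariate reversed log2 fold changes against ebf3 GFP-positive cells for si:dkey-4e7.3 (1 of 2) (-7.655), krt15 (-11.996), col1a2 (-0.136) and si:ch211-237l4.5 (-2.144) in wdr12 GFP-positive cells, and for foxm1 (-0.361), kcnj8 (-0.144) and col1a2 (-0.197) in wdr12 GFP-negative cells; the cause was not tested. A stricter threshold gives fewer calls by construction: at an adjusted p under 0.01, 823 higher and 933 lower between the sorts of the wdr12 line, 1052 lower against ebf3 GFP-positive cells, 195 and 79 between the controls, and 520 and 643 against both controls. Between the controls the counts were 767 and 610 at an adjusted p under 0.1, 788 and 704 with the Wald test of DESeq2, 852 and 753 with only the 2 groups compared in the fit, 819 higher with the replicate block, and 1037 and 900 without wdr12 GFP-positive replicate 1 and ebf3 GFP-positive replicate 3 together; the cause was not tested beyond the threshold. Leaving out each library gave 557 to 1752 higher and 785 to 1832 lower between the sorts of the wdr12 line, 133 to 753 and 25 to 576 between the controls, and 473 to 1009 and 640 to 1387 against both controls, with the lowest counts where 1 wdr12 GFP-negative library was left out and its group held a single library. With an estimated correlation 0, 0 and 0 gene lists passed in the 3 comparisons, against 11, 16 and 14 with camera's preset correlation. The mean r between replicates was 0.957, 0.971 and 0.965 for wdr12 GFP-positive, wdr12 GFP-negative and ebf3 GFP-positive cells with log2(CPM + 5), 0.932 for wdr12 GFP-positive cells with at least 10 counts in every library, and 0.935 to 0.94 for wdr12 GFP-positive and 0.922 to 0.961 for ebf3 GFP-positive cells with a library left out. The replicate block also ended the call of the ribosomal protein list against ebf3 GFP-positive cells in wdr12 GFP-positive cells (adjusted p = 0.0779) and brought the DNA repair (adjusted p = 0.0255) and mature neuron and synapse (adjusted p = 0.0426) lists past the threshold between the controls. Correlations of deviations between replicates with the same number ran from -0.242 to 0.209. The deviations of a group sum to 0, and those of 2 libraries mirror each other, so these few values cannot exclude pairs. The numbers were not read as pairs in the main fit. Over all alternatives, values of named genes kept their direction and side of the threshold in 3203 cases, were lost in 276, gained in 6 and reversed in 7, and list results were kept in 721, lost in 53 and gained in 6. The planned filters and Benjamini-Yekutieli adjustment of the authors' tables were not run, because counts of all groups were at hand. Depth and spread limit all calls, but how far they do so for 2-fold changes was not measured. At most 4% of simulated 2-fold changes were called, with only 200 genes changed, a stricter setting than the real comparisons.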

Other observations

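The test of 1 ratio over the erythrocyte genes was chosen before its result was seen; all other tests below, and the transmitter and liver genes, were chosen after, and the bound against free RNA was narrowed once after its result was seen and then set back. Of 7 transmitter genes looked at, 3 of GABA signalling were higher in wdr12 GFP-negative than in ebf3 GFP-positive cells and 4 of glutamate and acetylcholine signalling were not called, and no difference between these classes was tested. gad1b, the main enzyme of GABA synthesis, stood at 42.3 ± 32.6 CPM in wdr12 GFP-positive (SD, n = 3), 328 ± 34.2 in wdr12 GFP-negative (n = 2) and 67.1 ± 17.7 in ebf3 GFP-positive cells (n = 3). Between the controls its log2 fold change was 2.29 ± 0.46 (adjusted p = 0.0095), with 2.13 ± 0.41 for gad2 (adjusted p = 0.00758) and 1.56 ± 0.30 for the vesicular transporter slc32a1 (adjusted p = 0.0071). Each call was lost without wdr12 GFP-negative replicate 1 (adjusted p = 0.0509 for gad1b, 0.0757 for gad2 and 0.0851 for slc32a1) and replicate 2 (0.0797, 0.091 and 0.0722), and those of gad1b and slc32a1 also without ebf3 GFP-positive replicate 1 (0.0653 and 0.0538). slc17a6a, slc17a6b, CHAT (2 of 2) and SLC18A3 had log2 fold changes of -0.52, -0.37, -0.64 and -0.67 between the controls (adjusted p = 0.502, 0.669, 0.473 and 0.506).

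Published lists that the authors set beside their results overlapped the authors' sheet of genes higher in wdr12 GFP-positive cells. Of 209 human genes listed for activated astrocytes 199 were also in that sheet, as were 92 of 94 for quiescent astrocytes, 215 of 230 and 103 of 129 for neuroblasts, and 102 of 133 for quiescent neuroepithelium. These lists were given only for genes the authors selected, so the shares say nothing about the rest of each list.

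Red blood cell genes were higher in wdr12 GFP-negative cells than in both other groups. Erythrocytes or their RNA may be a source. A gate on GFP would remove such cells from the GFP-positive groups but not from this one, although it need not remove free RNA. The erythrocyte list had an adjusted p = 0.000645 between the sorts in the list test, and adjusted p = 0.382 with an estimated correlation. A globin GB (ENSORLG00000003046) stood at 34610 CPM, and all 10 list genes carry symbols through the authors' selection from these libraries. A test set beforehand asked whether 8 called members kept 1 ratio between the GFP-negative libraries: the SD of their log2 ratios was 0.827 against a median of 0.432 in random sets (percentile 96.1), which met the bound written against it. All 8 members were higher in replicate 2 than in replicate 1 (log2 ratios from 0.521 to 2.564, median 1.943). Those of slc4a1a, ALAS2, cahz and nt5c2l1 lay close together, from 2.177 to 2.564. That of blvrb was 1.708, and HBZ, tfr1a and sptb were lower at 0.782, 0.521 and 0.843. The other called genes hardly moved (median 0.133, SD 0.514), so random sets of them are a poor reference for genes that all rise. With the mean level of the other groups subtracted, the SD of the 8 members was 0.728. The test argues at most against RNA of 1 source in fixed proportions, and is weak evidence against erythrocytes as such. A source of differing composition was not tested. A few genes taking most of the counts is argued against, since the 10 most abundant genes took at most 20.85% of a library, which can shift other genes by 0.337 on the log2 scale against a list median of -4.53, while a difference in the blood content of the tissue was not tested.

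Liver and plasma protein genes were higher in wdr12 GFP-positive than in ebf3 GFP-positive cells, with a median log2 fold change of 5.65 for secreted and 3.53 for intracellular proteins. All 14 genes were listed by the authors as changed in these libraries, and apoa2 and tfa were the most abundant at 35479 and 26462 CPM. Liver cells or their RNA may be a source. The GFP gate would remove such cells unless they fluoresce, but it need not remove free RNA. The SD of log2 ratios of replicate 3 over replicate 1 was 0.79 against a median of 0.929 in random sets, at percentile 22.6. This lay between the bounds set for and against this source. Free RNA at an equal share of the counts in both sorts would give a median near 0 between them. The median was 2.128, which met the bound set against such an equal share. Normalised shares were 3.104% to 13.02% in GFP-positive and 1.888% to 2.071% in GFP-negative libraries. A share also depends on the cellular RNA in each library, which is not given, so free RNA as such is not argued against. Only 7 of the 14 genes were called higher between the sorts and none lower, and C3 (3 of 4) had a log2 fold change of -0.60. The raw share of GFP-positive replicate 1 (2.47%) also lay below that of GFP-negative replicate 1 (2.72%). The genes were also higher in wdr12 GFP-negative than in ebf3 GFP-positive cells (median 3.498), so a difference between the lines or their dissections cannot be told apart from one between the cells.

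ebf3 GFP-positive replicate 3 stood apart from the other two libraries of its group. Its log2 ratio to their mean had a median of 1.262 for radial glia, 1.372 for oligodendrocytes, 0.705 for microglia, 0.04 for meninges, 1.517 for liver genes, 0.833 for stress and immediate early genes (17 of 22 above 0) and 0.732 for Hedgehog and Fgf genes. More RNA of other cell types in that library may be the source, but the meninges list, the lowest at 0.04, lay between the bounds set for and against it, so this stays open, as does a difference in handling, which was not tested; sorting for GFP would remove such cells, and all list genes were chosen by the authors on these libraries. For the count of genes against ebf3 GFP-positive cells, the real split of the 6 libraries called 3671 and the highest of the other splits 0; 1 of 10 splits gave as many, and 10 splits cannot give a share under 0.05.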
